A study of Homo sapiens with 5 samples.

How the data were processed

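Total RNA of BxPC-3 cells was amplified linearly, reverse transcribed and labelled with Cy5 and Cy3 for hybridisation to oligonucleotide arrays, per the labels' protocols. The deposited values are one log ratio per probe and array for 21328 probes, and were taken as log2 ratios. Their base, the scanner, the background correction, the normalization and the filter that left values empty are not given in the sources used here. Base 10 was taken as unlikely, since the largest value, 5.96, would exceed the range of a 16-bit scanner, which spans 4.82 on that scale. That value is from 1 probe with no gene listed and a value on 1 array only. With the background correction and normalization unknown, ratios need not stay within that range, so base 10 is not ruled out. Natural logs could not be ruled out either, and all folds depend on this choice. The labels name both dyes for each channel, so the direction is unstated as well. Channel 1 over channel 2 was taken as the likely direction, because SMAD2 and 2 of 3 SMAD3 probes were low in their own knockdown and the TGF-β direct targets were high in the treated wild-type cells. The column medians were −0.0243, 0.00223, 0.00307, 0.0260 and 0.0416 for the wild-type, Smad2 knockdown and Smad3 knockdown responses and the Smad2 and Smad3 knockdown over wild type, in that order. Values were used as deposited, without further centring.

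Between 10119 and 10802 probes had a value on an array. 8541 had one on all 5 arrays and 9087 on none. The number of arrays limits the precision, and no signal was available to tell dim from bright probes. By the platform annotation, 16869 probes carry 1 gene symbol, 172 several and 4287 none listed. Symbols were looked up by gene ID in a RefSeq gene table of assembly GRCh38.p14, where 16778 matched and 91 kept the platform symbol. No coordinates were taken from it. A gene's value is the mean over its probes with 1 symbol, which gave 9932 genes with a value on any array and 7310 on all 5. SMAD4, SMAD7 and MMP9 have probes without values.

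Each comparison has 1 array, so genes were sorted by size alone, at log2 ratios of 1 or more (2-fold) and at 1.5-fold. A smaller response in a knockdown line was counted for wild-type responders whose log2 ratio moved against the wild-type direction by at least the size rule. Reversals of sign therefore count as reductions, although the plan named a response smaller in size. Shared genes are given beside the product of the list sizes over the genes measured in both. Gene lists, 25 in number, were summarised by the median and its percentile among 10000 random lists of the same size, not matched on expression, which describes these arrays only. The lists cover TGF-β direct targets (40 genes, 27 of them also in another list), TGF-β and SMAD pathway components, ID and BMP targets, EMT mesenchymal genes, epithelial genes, extracellular matrix, invasion proteases and inhibitors, integrins and adhesion, immediate early and AP-1 genes, MAPK feedback and EGF ligands, cell cycle, growth arrest and apoptosis, NF-κB targets and cytokines, interferon-stimulated genes, hypoxia and glycolysis, cholesterol and lipid synthesis, unfolded protein response, cytoskeleton and motility, ribosomal proteins, oxidative phosphorylation, common reference genes, and haematopoietic, fibroblast, endothelial and neural markers.

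The groups, size rules, gene lists, the alternatives listed below, apart from 2, and the rule for named genes were fixed before the data were examined. That rule takes the 10 highest and 10 lowest genes of each array that have a proper symbol, list members at 2-fold, the 10 largest reductions per knockdown line, and SMAD2, SMAD3, SMAD4, SMAD7, JUNB, CDH1, VIM, MMP2, MMP9 and PLAU, with a further gene that is not reported here. Other list members and DKFZP761N09121 were chosen as examples after their values were seen. The correlation that shared RNA gives was simulated with equal noise in each RNA, and that of ribosomal and oxidative phosphorylation genes was set among 10000 random gene sets of the same size. Untreated knockdown over untreated wild type was derived as the wild-type response plus treated knockdown over treated wild type minus the knockdown response.

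The alternatives were median-centred arrays, arrays scaled to 1 spread, 1.5-fold and 3-fold rules, the probe with the largest wild-type ratio or each probe alone in place of the mean, probes with values on all 5 arrays, genes with 2 or more probes that match in sign, responders by rank, Spearman's rho, list means, lists without shared members, and arrays without their extreme values. Natural logs and responders chosen without wild-type RNA were added after the data were seen. The size rule was tested on simulated data: of 200 genes moved 2.5-fold, it recovered 178 among 8724 genes with the spread of the wild-type response and 197 among 8561 with that of the Smad3 knockdown response, with 0 other genes called. A log2 ratio of 1 lies far outside the gene SD of these arrays (0.237 and 0.136), so that 0 was close to fixed in advance. It does not measure false calls in the real arrays, where probes of 1 gene can differ widely (PLD1 at 0.22 and −2.58). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.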

Results

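Gene expression was measured in BxPC-3, a cell line established from a human pancreatic adenocarcinoma, on 5 dual-colour oligonucleotide arrays. BxPC-3 carries a deletion of SMAD4, the partner through which the receptor-activated factors SMAD2 and SMAD3 usually act on their target genes. Wild-type cells, cells with a Smad2 knockdown and cells with a Smad3 knockdown were kept for 4 h with or without 10 ng/ml TGF-β. On 3 response arrays, treated RNA of each line was set against untreated RNA of the same line. On the other 2 arrays, treated knockdown RNA was set against treated wild-type RNA. The labels call those wild-type cells WT (control), and WT on the response array. That RNA of the same kind is 1 preparation on all arrays is not stated and is assumed throughout. Each comparison has 1 array, so no difference has a replicate check and no p-value is given. Values were present for 8724 genes in the wild-type response, 8994 in the Smad2 knockdown response and 8561 in the Smad3 knockdown response. The arrays against treated wild type gave 8422 genes for the Smad2 knockdown and 8764 for the Smad3 knockdown. Log2 ratios of probes of the same gene differed with a standard deviation of 0.22, 0.21, 0.15, 0.21 and 0.21 on these arrays in that order, which is the only measure of error inside them. The base of the logarithm and the direction of the ratios are unstated, and folds below assume base 2 and the likely direction of the first-named over the second-named RNA.

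The values of the targeted genes also served to choose the direction of the ratios, so their sign is no independent check of it. SMAD2 had a log2 ratio of −0.85 in treated Smad2 knockdown over treated wild-type cells. In the likely direction that is 55.6% of the wild-type level, or 42.8% if the values are natural logs; in the other direction it would be 1.80-fold of wild type. On the array of treated Smad3 knockdown over treated wild-type cells, 2 SMAD3 probes read −0.72 and −0.74, or 60.6% and 60.0% of wild type in the likely direction and 1.65-fold and 1.67-fold in the other. A further SMAD3 probe, which had a value on that array alone, read 0.73, so that the mean over the 3 probes was −0.24. SMAD3 was at 0.00 in the Smad2 knockdown, while SMAD2 was at −0.37 in the Smad3 knockdown. The SMAD4 and SMAD7 probes had no value on any array. TGF-β left both targeted genes near their untreated level in their own knockdown line, with SMAD2 at 0.09 in the Smad2 knockdown and SMAD3 at 0.06 in the Smad3 knockdown. The 0.06 is a mean of probes at −0.11 and 0.23. In wild-type cells SMAD2 was at 0.33 with TGF-β and SMAD3 at 0.12. The SMAD2 ratios of −0.85 and −0.37 are against treated wild-type RNA, so part of them can lie in that wild-type rise.

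In wild-type cells, the question was which genes answer TGF-β without SMAD4. After 4 h, 18 genes were 2-fold or more higher and 0 were 2-fold or more lower. At the top stood the fructose transporter gene SLC2A5, with a log2 ratio of 1.77 (3.41-fold), followed by PMEPA1, a TGF-β-induced gene whose protein dampens SMAD signalling, at 1.36 (2.56-fold). ITGB6, which encodes the β6 subunit of an integrin that activates latent TGF-β, was at 1.36, with its 2 probes at 1.73 and 0.99. PTGS2, the inducible cyclooxygenase, was at 1.28, the sialomucin PODXL at 1.16, the bisphosphoglycerate mutase BPGM at 1.12, the cadherin CDH6 at 1.05 and the cytokines IL1A and CXCL8 at 1.02 and 1.01. ZNF18 at 1.34, EEIG2 at 1.19, GPR157 at 1.12 and MMD at 1.09 complete the 10 highest. Among the lowest were ZNF488 at −0.94, ZNF598 at −0.84, CCDC102A at −0.82, GPRC5C at −0.81, BTN3A3 at −0.78, the double-stranded RNA sensor IFIH1 at −0.78, RIBC2 at −0.77, the vesicular amine transporter SLC18A2 at −0.74, the aldehyde dehydrogenase ALDH3A1 at −0.73 and the tight-junction gene CLDN1 at −0.72.

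By group, the TGF-β direct targets stood highest in wild-type cells, with 26 of 30 measured members above 0 and a median of 0.28, above all 10000 random lists of the same size. The sign of this list was used to choose the direction of the ratios and does not test it. Beside PMEPA1 and ITGB6, 4 members were 1.5-fold or more higher: the cell cycle inhibitor CDKN1A at 0.70, BHLHE40 at 0.64, ADAM19 at 0.62 and SNAI2, which encodes the repressor Slug, at 0.60. Targets of NF-κB, cytokines and chemokines had a median of 0.20 (percentile 99.94), led by PTGS2, IL1A and CXCL8, with IL1B at 0.79. Growth arrest and apoptosis genes had a median of 0.18 (percentile 99.89), among them CDKN1B at 0.63 and PMAIP1 at 0.58, but 0.02 with probes valued on all 5 arrays and 0.10 without members of other lists. TGF-β and SMAD pathway components had 0.11 (percentile 99.58), with the receptor gene TGFBR1 at 0.46. Epithelial genes lay below other genes at −0.16 (percentile 0.21), with CLDN1, ELF3 at −0.48, the splicing regulator ESRP1 at −0.45 and CLDN4 at −0.44, against TJP1 at 0.78 and CDH1, E-cadherin, at 0.30. Interferon-stimulated genes were lowest, at −0.20 (percentile 0.01), with IFIH1, IRF1 at −0.48, OAS2 at −0.47 and OAS1 at −0.41. Of 26 measured members 21 were below 0, against B2M at 0.83. Of the other genes followed throughout, VIM was at 0.17, JUNB at 0.15 and PLAU at 0.25. With all arrays scaled to 1 spread, 8 genes in place of 18 reached 2-fold higher.

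In Smad2 knockdown cells, TGF-β gave 13 genes 2-fold or more higher and 2 lower. Of the 15 wild-type responders measured here, 5 were again 2-fold higher: PMEPA1 was at 1.40, ITGB6 at 1.29, BPGM at 1.14, AP4S1, an adaptor complex subunit, at 1.10 and SLC2A5 at 1.06. The ITGB6 value is from 1 probe, which read 1.73 in wild type, where the gene value of 1.36 is a mean of 2 probes. Independent lists would share 0.0144 genes. The gelatinase gene MMP2 was at 1.24, STX1A at 1.29, the fatty acid amide hydrolase FAAH at 1.05 and TMEM260 at 1.03. The immunoglobulin gene IGHM had the highest ratio, 3.16, on a probe without a value on any other array, as was also so for MMP2, TMEM260 and 2 more of the 15 genes. The lowest were PLD1 at −1.18, a mean of probes at 0.22 and −2.58, SERPINA6 at −1.05, the kallikrein KLK12 at −0.98, EXTL2 at −0.89, the mucin MUC13 at −0.87, SRGAP3 and CHRNA7 at −0.86, IPO7 and RHOV at −0.84 and EEA1 at −0.81.

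The TGF-β direct targets had a median of 0.22 in Smad2 knockdown cells, with 25 of 32 above 0 and a percentile of 100. CDKN1A was at 0.86, BHLHE40 at 0.44 and ITGA2 at 0.43, whereas SNAI2 was at 0.13 and ADAM19 at −0.05. Integrins and adhesion genes had a median of 0.11 (percentile 99.83), with ITGB6, CD151 at 0.83 and ITGA5 at 0.59, but 0.04 without members of other lists. Cell cycle genes had −0.08 (percentile 0.40), with CDC25A at −0.57, and interferon-stimulated genes −0.10 (percentile 0.49). Haematopoietic markers had a median of 0.18 over 8 measured members (percentile 99.23) and fibroblast and stellate cell markers 0.18 over 6 (percentile 98.89). CDH1 and VIM were each at 0.09, JUNB at 0.26 and PLAU at 0.32.

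In Smad3 knockdown cells the ratios were smaller: 1 gene was 2-fold or more higher and 4 were lower, and 9 and 10 passed 1.5-fold. The highest was SLC18A2 at 1.02, followed by PMEPA1 at 0.77, SLC2A5 at 0.77, BPGM at 0.71, ITGB6 at 0.66, AP4S1 at 0.65, the formin FMNL1 at 0.65 and PODXL at 0.59, then ACADS at 0.54 and PRR11 at 0.52. The lowest were the T-cell surface gene CD2 at −1.62, CCDC102A at −1.27, LRIG1, an inhibitor of EGF receptor signalling, at −1.05, TBC1D16 at −0.95, TMEM59L at −0.73, COL9A2 at −0.70, CLDN1 at −0.63, NBAS and SLC39A14 at −0.60 and APIP at −0.58. The TBC1D16 value is a mean of 2 probes that differed in sign. An unnamed transcript, DKFZP761N09121, was at −1.18. CLDN1 was lower by a like amount in the other lines, at −0.72 in wild-type and −0.70 in Smad2 knockdown cells.

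The direct targets had a median of 0.14 in Smad3 knockdown cells, with 22 of 30 above 0 and again a percentile of 100, or 0.09 without members of other lists. CDKN1A was at 0.40, SNAI2 at 0.28, ADAM19 at 0.17, BHLHE40 at 0.16 and TGFBI at −0.01. Immediate early and AP-1 genes had a median of 0.10 (percentile 99.74), with JUNB at 0.13 and JUN at 0.13, and a mean of 0.06. Cell cycle genes had −0.06 (percentile 0.21), with CENPE at −0.47, CENPF at −0.46 and MCM6 at −0.44, and a mean of −0.10. Common reference genes had −0.11 (percentile 0.32), with IPO8 at −0.50 and the transferrin receptor TFRC at −0.43. Ribosomal protein genes had −0.06 (percentile 0.37), with a mean of −0.03 and a direction that turned to 0.01 with probes valued on all 5 arrays. With arrays scaled to 1 spread the AP-1, cell cycle, reference and ribosomal medians were 0.15, −0.10, −0.18 and −0.10, and that of the direct targets was 0.21. CDH1 was at 0.05, VIM at 0.06 and PLAU at −0.06. The gene values of this array had a standard deviation of 0.136, against 0.237 in wild type, and with all arrays scaled to 1 spread it gave 8 genes higher and 8 lower.

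**Figure D1:**
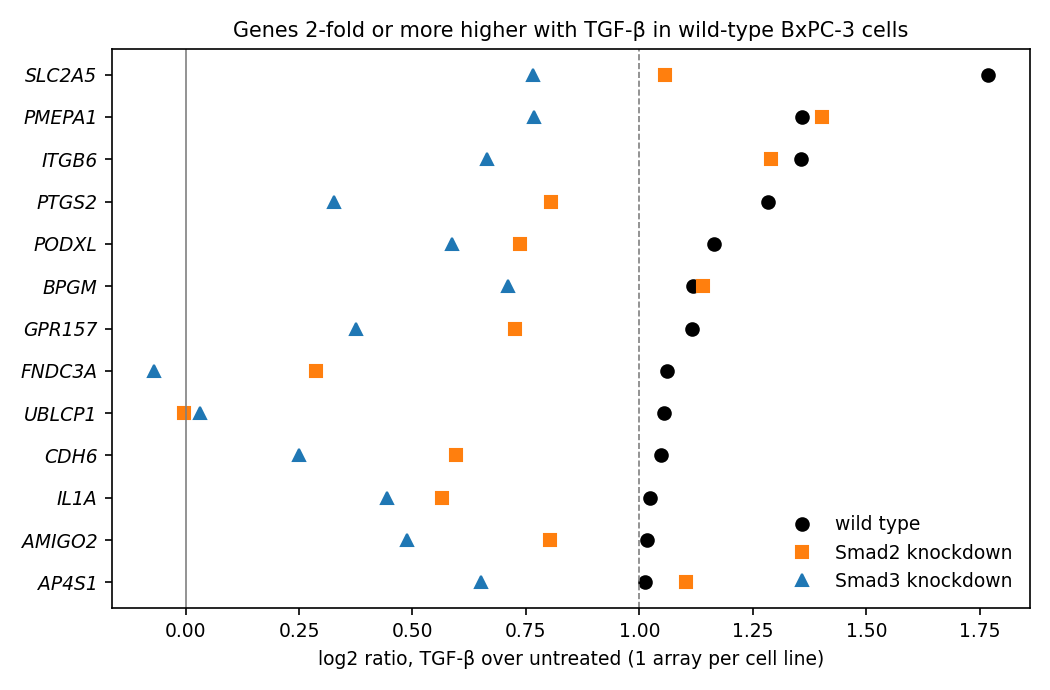
Log2 ratio of TGF-β over untreated RNA for the 13 named genes that were 2-fold or more higher in wild-type cells and had a value in all 3 lines, with 1 point per line and 1 array per line; the dashed line marks 2-fold. Smad3 knockdown points lie left of the wild-type points for 13 of 13 genes, and Smad2 knockdown points for 10 of 13. The wild-type point of ITGB6 is a mean of probes at 1.73 and 0.99, and its knockdown points are from the first probe alone.

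The labels sort genes as dependent on or independent of each factor, so the wild-type responders were read in both knockdowns. Of the 18 genes 2-fold higher in wild type, 15 were measured in the Smad2 knockdown response, where their median was 0.74 and 5 were again 2-fold higher. In the Smad3 knockdown response 14 were measured, with a median of 0.47 and 0 at 2-fold. The order turned in wider choices, with 0.04 and 0.12 for genes chosen at 1.5-fold and 0.02 and 0.11 for the 200 highest by rank. With arrays scaled to 1 spread the medians were 1.04 and 1.01. Scaling also changed the choice, since 8 genes in place of 18 then reached 2-fold in wild type. PTGS2 was at 0.81 and 0.33 in the Smad2 and Smad3 knockdown, GPR157 at 0.73 and 0.38, CDH6 at 0.60 and 0.25, IL1A at 0.57 and 0.44 and AMIGO2 at 0.80 and 0.49. Genes picked as extreme on an array are less extreme on the next through noise alone. The reverse choice, the 13 genes 2-fold higher in the Smad2 knockdown, gave a wild-type median of 1.07 over 8 measured genes, and a Smad3 knockdown median of 0.66 over 7. At 1.5-fold, the same choice gave 0.31 over 50 genes and 0.15 over 56. Over the 30 direct targets, the Smad3 knockdown response was below the wild-type response for 23 and the median difference was −0.19 (percentile 0.06). The Smad2 knockdown response was below it for 16, with a median difference of −0.03 (percentile 17.46). With arrays scaled to 1 spread these differences became −0.06 (percentile 23.1) and 0.05 (percentile 78.8), so the Smad3 difference is lost when the spread of the arrays is made equal.

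A gene counted as reduced if its log2 ratio moved by 1 or more against the direction of its wild-type response. Reversals of sign thus count, even where the opposite ratio is larger, as for SLC18A2 below. By this rule, 3 of the 15 wild-type responders were reduced in the Smad2 knockdown, CXCL8 (−0.44), UBLCP1 (0.00) and DKFZP761N09121 (−0.70). In the Smad3 knockdown 4 of 14 were reduced, SLC2A5 (0.77), FNDC3A (−0.07), UBLCP1 (0.03) and DKFZP761N09121 (−1.18). Of these, 2 and 3 had a value in treated knockdown over treated wild-type cells, where DKFZP761N09121 was 2-fold lower in both, at −1.48 and −1.65. With each probe on its own, 4 and 6 genes were reduced, and ITGB6 joined the Smad3 set and was lower there too (probe at 1.73 in wild type, 0.66 and −1.16). At 1.5-fold, 91 of 181 wild-type responders, higher or lower, were reduced in the Smad2 knockdown and 82 of 169 in the Smad3 knockdown. Of the 79 and 72 of those with a value on the arrays against treated wild type, 31 and 22 were matched there. The 31 hold many ribosomal and oxidative phosphorylation genes, such as RPL31, RPL34, RPS24, RPS27, COX7B and UQCRB, beside CDKN1B. Among the 22 are ITGB6, PMEPA1, PTGS2, IL1B and THBS1, and PSMA2 and SNRPE are in both sets. The counts thus do not rank the lines by their loss of TGF-β targets. Treated wild-type RNA is on both arrays behind each match. The other genes with the largest reductions were, for Smad2, MTMR9 (0.88 in wild type and −0.41 in the knockdown), CRYZ (0.69 and −0.50), TMEM59L (0.93 and −0.25), MRPL35 (0.73 and −0.41), CASTOR1 (0.73 and −0.40), CCDC102A (−0.82 and 0.30), MTFR1 (0.71 and −0.38) and the connexin gene GJA1 (0.95 and −0.12). For Smad3 they were SLC18A2 (−0.74 and 1.02), TMEM59L (−0.73), CASTOR1 (−0.44), ZNF598 (−0.84 and 0.14), PTGS2 (1.28 and 0.33), B2M (0.83 and −0.12) and SEM1 (0.84 and −0.08). CCDC102A was at −0.61 in treated Smad2 knockdown over treated wild type, lower there rather than higher.

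Treated Smad2 knockdown cells were compared directly with treated wild-type cells. There, 12 genes were 2-fold or more higher and 9 lower. The highest were PGC, the pepsinogen C gene, at 1.39, the collagenase MMP13 at 1.34, the FGF-binding protein FGFBP1 at 1.33, the gap-junction gene GJB2 at 1.15, CTHRC1 at 1.14, the Notch ligand DLL1 at 1.13, WNT10A at 1.13, the interferon-induced IFITM1 at 1.11, SLC18A2 at 1.10 and the cytokine IL32 at 1.06. The lowest were GAGE1, a cancer-testis antigen gene, at −1.34, NBPF4 at −1.27, CAMK2N1 at −1.25, the replication kinase CDC7 at −1.07, RPS24 at −1.04, EXOSC9 at −1.03, RPL36A at −1.02, PSMA4 at −1.01, and the chaperone HSP90AA1 and MRPL13 at −0.98. PTGS2, PODXL and ITGB6 were close to the wild-type level or above it, at 0.21, 0.29 and 0.08.

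Cholesterol and lipid synthesis was the group farthest from 0 in treated Smad2 knockdown cells, with a median of 0.40 over 16 genes (percentile 100), 15 of them above 0. The desaturase SCD was at 0.94, DHCR7 at 0.84 and the regulators SREBF1 and SREBF2 at 0.61 and 0.52. NF-κB targets and cytokines had 0.21 (percentile 100), with NFKB1 at 0.50 and IL1B at 0.28. Extracellular matrix genes had 0.15 (percentile 99.79), with fibronectin, FN1, at 0.43. Interferon-stimulated genes had 0.13 (percentile 99.41), with IFITM1, IFI27 at 0.79, BST2 at 0.79 and ISG15 at 0.53. Cell cycle genes had −0.13 (percentile 0.02), with RFC4 at −0.72, BUB1B at −0.68 and CDK1 at −0.53, and ribosomal protein genes −0.13 (percentile 0.05), with RPS24, but −0.04 with probes valued on all 5 arrays. Common reference genes had a lower median than both, −0.17 (percentile 1.08), and oxidative phosphorylation genes had −0.08 (percentile 1.82). The proteases went both ways, MMP13 high and MMP7 at −0.80 and MMP1 at −0.68. The direct targets had a median of 0.10 (percentile 95.93), with JUNB at 0.40; CDH1 was at −0.16, VIM at −0.07 and PLAU at −0.09. With arrays scaled to 1 spread, 3 genes were 2-fold higher and 4 lower.

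In treated Smad3 knockdown over treated wild-type cells, 9 genes were 2-fold or more higher and 17 lower. The highest included the keratin genes KRT4 at 2.03 (4.09-fold) and KRT13 at 1.17 and the surface antigen gene LY6D at 1.86. SLC18A2 was at 1.27, SYT8 at 1.18, ALDH3A1 at 1.16, the lipase CEL at 1.07, RHOV at 1.06, the TGF-β family member GDF15 2-fold higher and PTK7 at 0.98. The lowest held several of the wild-type responders, PTGS2 at −1.19, ITGB6 at −1.16, PODXL at −1.15, EEIG2 at −1.12 and IL1A at −1.06. Responders were chosen as high in treated wild-type RNA, so noise in that RNA, if shared, would by itself make them low here. COXFA4L3 was lowest at −1.66, with LRIG1 at −1.23, SPRR2C at −1.14, SLC25A24 at −1.13, SEMA3C at −1.12 and NT5E, the ecto-nucleotidase CD73, at −1.09. TNFAIP3, the NF-κB inhibitor A20, was 2-fold lower, THBS1 at −0.90, VIM at −0.71, TGFBI at −0.70, SNAI2 at −0.54 and ZEB1 at −0.50.

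By group, common reference genes had the lowest median in treated Smad3 knockdown cells, −0.17 (percentile 0.83). Interferon-stimulated genes had −0.15 and the lowest percentile of the 25 lists (0.15), with IFI6 at −0.55 and IFIT1 at −0.42. NF-κB targets and cytokines also had −0.15 (percentile 0.56). Direct targets had a median of −0.04 and a mean of −0.11 (percentile 5.60 for the median), or a median of −0.28 without members of other lists, and 3 of 30 were 1.5-fold or more lower, ITGB6, TGFBI and PMEPA1 at −0.63. Cholesterol and lipid synthesis had 0.18 (percentile 99.12), with SCD at 0.52. Among proteases and their partners, the MMP inducer BSG was at 0.85 and the cathepsin CTSD at 0.62, MMP1 was at −0.65 and PLAUR at −0.49. CDH1 was at −0.25, JUNB at 0.13 and PLAU at −0.01. Scaling to 1 spread left 3 genes 2-fold higher and 5 lower.

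**Figure D2:**
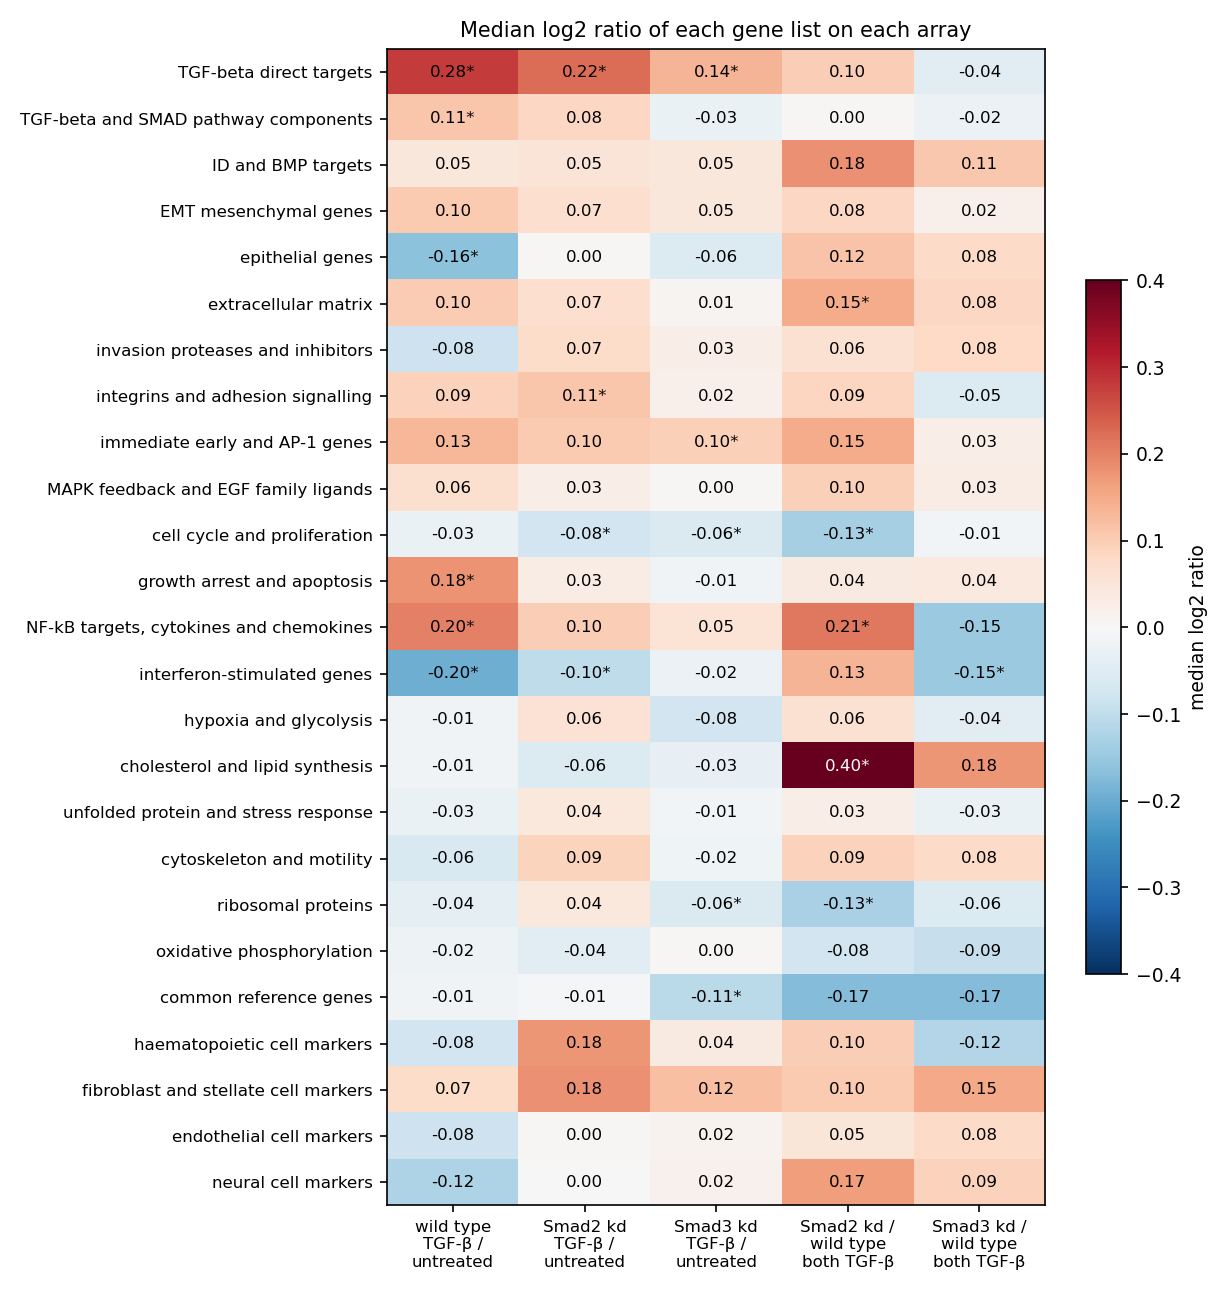
Median log2 ratio of the measured members of 25 gene lists on the 5 arrays, from blue (below 0) to red (above 0), with an asterisk where the median lay among the lowest or highest 0.5% of 10000 random lists. TGF-β direct targets were at 0.28, 0.22 and 0.14 on the response arrays, and lipid synthesis at 0.40 in treated Smad2 knockdown over wild-type cells.

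The remaining lists lay outside the lowest and highest 0.5% of random lists on every array. In wild-type cells, EMT mesenchymal genes had a median of 0.10, ID and BMP targets 0.05, invasion proteases and inhibitors −0.08, MAPK feedback and EGF ligands 0.06, hypoxia and glycolysis −0.01, the unfolded protein response −0.03, cytoskeleton and motility −0.06 and oxidative phosphorylation −0.02. For cell types that could be mixed in, the medians were −0.08 for haematopoietic, 0.07 for fibroblast, −0.08 for endothelial and −0.12 for neural markers, over 5, 5, 8 and 3 measured genes. In the Smad3 knockdown response, fibroblast and stellate cell markers had 0.12 over 5 measured genes (percentile 98.06). Of the 125 medians, 21 lay among the lowest or highest 0.5% of random medians, where 1.25 would do so by chance among independent lists.

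Across genes, which are not replicates, the wild-type response correlated at −0.469 with treated Smad2 knockdown over treated wild type and at −0.572 with the Smad3 counterpart, and those arrays correlated with each other at 0.548. All 3 pairs hold treated wild-type RNA, taken here as 1 shared preparation. Simulated unchanged groups that share it, with equal noise in each RNA, gave −0.495, −0.506 and 0.504. The covariances were −0.0272, −0.0334 and 0.0345, where noise of the size seen through the shared treated knockdown RNAs would give −0.00486, −0.00486 and 0.00486. For the Smad2 and Smad3 pairs that share treated knockdown RNA, the same simulation gave 0.490 and 0.496, but the arrays correlated at 0.121 and 0.124. Equal noise thus fails for those pairs, and the simulated values do not settle what shared RNA alone gives. Response arrays of different lines share no RNA. They correlated at 0.0599 for wild type with Smad2 knockdown, 0.103 for wild type with Smad3 knockdown and 0.199 for the knockdowns, and Spearman's rho was −0.0237, 0.0431 and 0.165. Of the ribosomal and oxidative phosphorylation genes, RPS24, RPS3A, RPL34, COX7B and 4 more were 1.5-fold or more higher in the wild-type response, while the medians of these lists were −0.04 and −0.02.

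**Figure D3:**
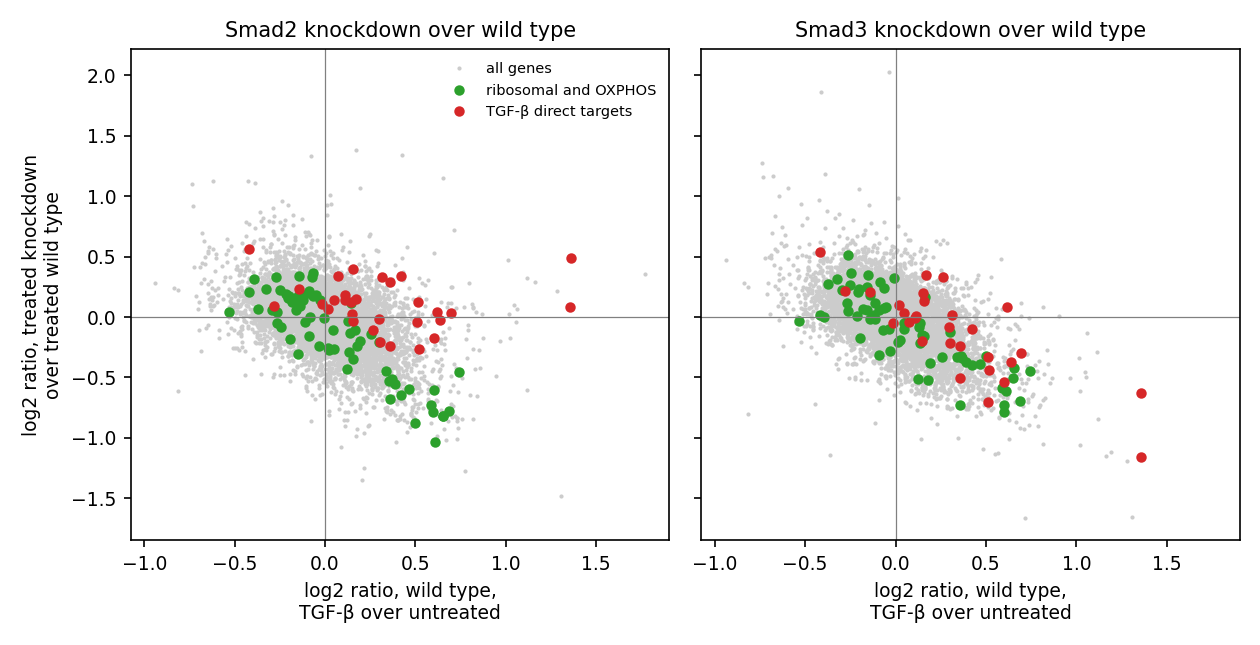
Log2 ratio of treated knockdown over treated wild-type cells against the wild-type response, with 1 point per gene; ribosomal and oxidative phosphorylation genes are green and TGF-β direct targets red. Both axes hold treated wild-type RNA, which alone gives a negative slope if it is 1 shared preparation. The green genes had r = −0.863 and −0.813, and random gene sets of the same size had medians of −0.482 and −0.574, while the highest red genes, PMEPA1 and ITGB6, lie above 0 for the Smad2 knockdown (0.49 and 0.08) and below 0 for the Smad3 knockdown (−0.63 and −1.16).

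Untreated knockdown cells were not set against untreated wild-type cells on an array, and the ratio was derived from 3 arrays, with the error of all 3. The sum takes RNA of the same kind as shared between these arrays. Smad2 knockdown cells then had 9 genes 2-fold or more higher and 6 lower before treatment, or 8 and 8 with each probe on its own. The 9 include PLD1 at 1.18, which rests on its probe at −2.58 that had a value in the Smad2 knockdown response alone. MMP13 was at 1.88, FGFBP1 at 1.61, GJB2 at 1.30, SCD at 1.07 and DLL1 at 1.06, with CCDC102A at −1.73 and CAMK2N1 at −1.38. Smad3 knockdown cells had 3 genes higher and 3 lower, KRT4 at 1.89, LY6D at 1.23 and PTK7 at 1.02 against SPRR2C at −1.62, COXFA4L3 at −1.37 and the cancer-testis gene CTAG2 at −1.13. The derived median of the cholesterol and lipid genes was 0.36 in the Smad2 line (percentile 100), and that of interferon-stimulated genes −0.19 in the Smad3 line (percentile 0.09). In the Smad2 line, NF-κB targets and cytokines had 0.22 (percentile 99.94) and direct targets 0.12 (percentile 99.6). Cell cycle genes had −0.14 there (percentile 0.39) and ribosomal protein genes −0.18 (percentile 0.27).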

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

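All tests in this part were chosen after the results were seen. Intervals come from 2000 bootstrap draws over genes, which are not replicates.

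Some genes went opposite ways in the lines, which was not tested. SLC18A2 was at −0.74 with TGF-β in wild-type cells and at 1.02 in Smad3 knockdown cells. TMEM59L was at 0.93 in wild type and −0.73 in the Smad3 knockdown. DKFZP761N09121 was at 1.31 in wild type, −0.70 in the Smad2 knockdown and −1.18 in the Smad3 knockdown. Probes outside the named genes also stood beyond every named probe. Probe H200016928, which lists several genes, read −1.36 in the wild-type response. Probe H200019171, with no gene listed, read −2.76 and −2.86 in treated Smad2 and Smad3 knockdown over treated wild type. Probe H200003459, with no gene listed and a value on that array alone, read 5.96 in treated Smad3 knockdown over wild type.

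The first pattern is the negative correlation across genes of the wild-type response with both treated knockdowns over treated wild type (−0.469 and −0.572), although 13 genes 2-fold higher in wild type had medians of 0.08 in the Smad2 and −0.63 in the Smad3 knockdown. A loss of the TGF-β response without Smad2 is argued against for the direct targets, whose Smad2 knockdown response differed from wild type by a median at the 17.46 percentile of random lists, although a partial loss stays open. A shift of the treated wild-type RNA outside the TGF-β targets may account for part of it: ribosomal and oxidative phosphorylation genes, which are in none of the TGF-β lists, correlated at −0.863 and −0.813, below all and at the 0.11 percentile of 10000 random gene sets, whose medians were −0.482 and −0.574. These lists were picked after results were seen, and the random sets were not matched on signal, which was not available. The percentiles thus do not set these genes apart from others of like signal. For the direct targets a need for Smad3 stays open too, at the 0.06 percentile, but scaling the arrays moved that to the 23.1 percentile. That shift alone leaves unexplained the −0.539 of these genes with the Smad2 knockdown response, which shares no RNA (0.01 percentile). With treated wild-type RNA assumed to be 1 preparation, the culture, the RNA and its labelling cannot be separated.

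The second pattern is the small spread of the Smad3 knockdown response. Compression of the whole array by 1 factor is open: probes of the same gene differed 0.535 times as much as in wild type and genes 0.556 times as much, a quotient of 0.963 (95% interval 0.788 to 1.14). A smaller response to TGF-β is also open, since 45 genes chosen at 1.5-fold in the Smad2 knockdown had a median difference of −0.23 from wild type (interval −0.35 to −0.17). The response arrays alone do not part these explanations.

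The third pattern is that the wild-type responders had smaller ratios in the Smad3 knockdown. For 13 genes 2-fold higher in wild type, treated Smad2 knockdown exceeded treated Smad3 knockdown cells on the 2 other arrays by a median of 0.64 (interval 0.46 to 1.12), in 13 of 13 genes. Treated wild-type RNA cancels if both arrays hold the same preparation. On that assumption, the excess argues against compression alone with equal starting levels for these genes. At 1.5-fold the excess was small, 0.09 over 104 genes (interval −0.02 to 0.19). Over untreated wild type, the sums of arrays put the 13 genes at 1.14 in treated Smad2 and 0.41 in treated Smad3 knockdown cells. A higher level of these genes before treatment in the Smad2 line is open, since it would raise the excess too. It was not derived for them as a set. The 15 measured responders had a median Smad2 knockdown response of 0.74, below that 1.14. Also open is compression together with a lower level before treatment in the Smad3 line. There, the derived starting level was −0.04 as deposited and −0.49 with expanded ratios (interval −0.83 to 0.15). The assumed factor itself makes that drop. A further hypothesis is that the response of these genes needs Smad3 more than Smad2. These arrays do not decide between these explanations.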

How the results depend on the processing

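Natural logs and responders chosen without wild-type RNA were added after the data were seen. Left out of the tally are 81 values that a setting cannot move, such as correlations on scaled arrays. Of 285 other values of leading results under alternatives, 181 stayed within the tolerance (a count within 1.5 times, a list median within 1 SD of random lists, a correlation within 0.1) and 104 moved. Of 162 values of other lists, 128 stayed, 33 moved and 1 reversed, the ribosomal list in the Smad3 knockdown response, which was 0.012 with probes valued on all 5 arrays. Median-centred arrays moved 0 values. With 1 array per comparison no replicate could be left out, and no paired analysis was possible because no group has replicates. Background, dim-probe and slide alternatives need scanner values, which were not analysed here. The cause of a change was not tested unless the setting itself makes it (a size rule, a log base or fewer genes).

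Counts are given in the order wild-type, Smad2 knockdown and Smad3 knockdown responses, then Smad2 and Smad3 knockdown over wild type, higher genes before lower ones. At 1.5-fold they were 147 and 56, 77 and 52, 9 and 10, 86 and 186, and 69 and 180. At 3-fold they were 1 and 0, 1 and 0, 0 and 1, 0 and 0, and 2 and 2. Read as natural logs, they were 74 and 14, 41 and 29, 4 and 7, 48 and 103, and 36 and 82. Scaling to 1 spread gave 8 genes higher in wild type, 8 and 8 in the Smad3 knockdown, 3 and 4 and then 3 and 5 against wild type. Probes valued on all 5 arrays left 5 and 0 in the Smad2 knockdown, 0 and 2 in the Smad3 knockdown and 6 higher in Smad2 knockdown over wild type. Genes with 2 or more probes of equal sign left 1 higher in wild type and 0 on the other arrays. The probe with the largest wild-type ratio gave 1 lower gene in wild type and 1 in the Smad2 knockdown, each probe alone gave 1 lower gene in wild type, and arrays without their extremes gave 1 lower gene in the Smad2 knockdown and 0 higher in the Smad3 knockdown.

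The median response of the wild-type responders, 0.74 in the Smad2 and 0.47 in the Smad3 knockdown, was 1.04 and 1.01 with scaled arrays, 0.040 and 0.12 at 1.5-fold, 1.06 and 0.77 for the 1 gene at 3-fold, 0.023 and 0.11 for the 200 highest by rank, and 0.17 and 0.23 with natural logs. The order of the knockdowns thus turned in the wider choices. With scaled arrays the choice was narrower, 8 genes in place of 18. Genes with a smaller response, reversals of sign counted, numbered 1 and 1 with scaled arrays, 91 and 82 at 1.5-fold, 0 and 0 at 3-fold and 37 and 36 with natural logs. The derived untreated Smad2 knockdown had 134 and 146 genes at 1.5-fold, 2 and 1 at 3-fold and 69 and 68 with natural logs, and the Smad3 knockdown 55 and 46, 1 and 1, and 20 and 19.

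The median of the direct targets with natural logs was 0.40, 0.32 and 0.20 in the 3 responses, −0.28 for Smad3 knockdown minus wild type and 0.25 for treated Smad2 over treated Smad3 knockdown. Without members of other lists it was 0.36, 0.31 and 0.089 in the responses, −0.28 in Smad3 knockdown over wild type and −0.29 for Smad3 knockdown minus wild type. The list mean was 0.30 in the Smad2 knockdown response, −0.11 in Smad3 knockdown over wild type and 0.24 for treated Smad2 over treated Smad3 knockdown. Scaling gave 0.21 in the Smad3 knockdown response, 0.046 for Smad2 knockdown minus wild type, whose sign turned, and −0.056 for Smad3 knockdown minus wild type. SMAD2 was at −1.22 in Smad2 knockdown over wild type with natural logs, and SMAD3 at −0.72 in its own knockdown with the probe of the largest wild-type ratio and with probes valued on all 5 arrays.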

Other observations

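The tests in this part were chosen after the results were seen. Subtracting the arrays against treated wild type compares treated Smad2 with treated Smad3 knockdown cells and removes the wild-type RNA if both hold the same preparation. Among the genes with the largest differences, COXFA4L3 (2.38), SPRR2C (2.02), MMP13 (1.60), GJB2 (1.56), PODXL (1.44), SEMA3C (1.43), PTGS2 (1.40), PGC (1.35), ITGB6 (1.24), IFI27 (1.13), PMEPA1 (1.12) and IL1B (1.03) were higher in the Smad2 knockdown. LY6D (−1.86), KRT4 (−1.74), FKBP4 (−1.05), the trefoil factor TFF2 (−1.04) and APOD (−0.99) were higher in the Smad3 knockdown.

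By group, NF-κB targets and cytokines differed most, with a median of 0.32 (percentile 100). Cholesterol and lipid synthesis had 0.27 (percentile 100), ID and BMP targets 0.21 over 7 genes (percentile 99.07), interferon-stimulated genes 0.19 (percentile 99.99), MAPK feedback and EGF ligands 0.18 (percentile 99.92), TGF-β direct targets 0.17 (percentile 100), integrins and adhesion 0.14 (percentile 99.97) and cell cycle genes −0.20, below all 10000 random lists. With arrays scaled to 1 spread the direct targets had 0.14, the NF-κB list 0.29, the interferon list 0.19, the lipid list 0.26 and the cell cycle list −0.16. The targets were also higher in the derived untreated Smad2 line, at 0.12, than in the Smad3 line, at 0.05, by an estimate that reuses the same arrays, and this difference was not tested.

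Choosing responders without wild-type RNA gave 7 genes that passed 1.5-fold in both knockdown responses, AP4S1, BPGM, FMNL1, ITGB6, PMEPA1, PODXL and SLC2A5. All 7 passed 1.5-fold in wild type, from 0.87 to 1.77 with a median of 1.16. Their medians were 1.10 in the Smad2 and 0.66 in the Smad3 knockdown response. Against treated wild type they had medians of 0.29 in the Smad2 knockdown and −0.74 in the Smad3 knockdown, where 6 of 6 measured were below 0.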
